A study of Homo sapiens with 4 samples.

How the data were processed

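Gene expression was measured in 4 established bladder cancer cell lines on 4 Agilent arrays read in 2 colours, 1 array per line. Per the labels, each array carried RNA of DMSO-treated cells in the Cy3 channel and RNA of the same line treated with 7.5 uM GSK126 in the Cy5 channel. HT1197 and HT1376 formed the ARID1A mutant group and T24 and 5637 the ARID1A wildtype group, as the series describes them. The lines served as replicates, 2 per group, and the labels do not say whether separate cultures were used. The limma p-values of single genes therefore rest on the spread between lines, which limma moderates toward that of other genes. The prior degrees of freedom of this moderation were 2.445 for all lines and 2.875 for the groups. The SE of a group pools the spread of both groups. The p-values of the gene lists, described below, also rest on the differences in effect across genes.

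The authors deposited the scanner output of Agilent Feature Extraction 9.5.1.1, made with the protocol GE2-v5_95_Feb07 and probe positions on hg18 (NCBI36). The deposited files give a mean spot intensity and a median local background intensity for each channel, with no normalisation. Per the file headers, a processed intensity per channel was made by spatial and multiplicative detrending and by linear and LOWESS dye normalisation within each array. The deposited log10 ratio is that of the processed Cy5 over the processed Cy3 intensity. A deposited p-value from Agilent's error model accompanies each log10 ratio of a single array. The deposited series matrix holds log2 ratios with repeated spots merged, and its normalisation method is not stated. Against the log10 ratios, converted to log2, over 22930 bright probes the matrix columns had slopes of -0.792 (HT1197), -0.741 (HT1376), -0.793 (T24) and -0.817 (5637), so the matrix is Cy3 over Cy5 and its sign was turned before use.

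Log2 ratios of GSK126 over DMSO were recomputed from the spot intensities with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, and each array was normalised by loess against brightness with control spots at weight 0. This assumes that most genes at each brightness are unchanged, so a ratio within an array shows unequal change among genes and not a change of total RNA. Spots marked as outliers by the scanner software were left out, 114 to 503 of 43376 per array, and the spots of a probe were averaged. Probes were kept if well above background in at least 1 channel on at least 2 of the 4 arrays and measured on all 4, which left 30351 of 41000. A gene was represented by its probe with the highest mean brightness, giving 22772 genes or features. Names came from the RefSeq gene table of assembly GRCh38.p14, used for names alone: 23958 probes matched by accession, 2755 by symbol and 1032 by an older symbol, and 13255 kept the name in the files. Of the tested genes or features, 14905 carried a current gene symbol. Features without one were tested but not named.

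No array was saturated at any probe spot, and the spike-in controls had observed against expected slopes of 0.831 (HT1197), 0.830 (HT1376), 0.850 (T24) and 0.877 (5637). The number of arrays limits the precision. The SD of log2 ratios among repeated spots of a probe was 0.0607 in HT1197, 0.0811 in HT1376, 0.0898 in T24 and 0.0757 in 5637. The dyes were not exchanged on any array, so a dye bias of a gene adds to the effect over all lines, and cancels in the comparison of the groups if it is common to all arrays. Both mutant lines were on 1 slide and both wildtype lines on another. No slide held both groups.

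The GSK126 effect over all 4 lines was tested with a limma intercept model (3 residual degrees of freedom). The effect in each group and the difference between groups were tested as contrasts of a group means model (2 residual degrees of freedom). Tests were two-sided, with empirical Bayes moderation and Benjamini-Hochberg adjusted p under 0.05 over the tested genes. The DMSO levels of both groups were compared in the same way on log2 Cy3 intensity after loess and quantile normalisation of the mean brightness between arrays. Genes at least 2-fold changed in 1 line, their overlap between lines and correlations across genes were counted without a test, as there is 1 array per line. The 27 gene lists were tested against all other genes with limma's camera at a preset correlation of 0.01, beside an estimated correlation. At the preset value genes count as almost independent, so these p-values do not measure the spread between lines alone. Limma's fry was run as well, which tests a list against no change and not against other genes. Each was adjusted by Benjamini-Hochberg over the lists. For each list the members passing over all genes and those passing when adjusted over the list alone were counted.

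The comparisons, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. That rule takes ARID1A, EZH2 and PIK3IP1 always, and per comparison the 12 highest and the 12 lowest genes that pass with the same sign in every line. Where fewer pass, the rest are genes with the same sign in every line, ranked by the smallest absolute log2 ratio over the lines, and their values are given without a call. For the difference, the lines of 1 group had to lie above those of the other. Within lists, members that pass or the 2 to 4 with the largest absolute mean are named, and per line the 3 highest and the 3 lowest genes. Some genes that these rules name are not reported here. List members that passed when adjusted over the list alone are also named, a choice made after their values were seen.

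The pipeline was tested on simulated data with 50 genes each changed by 1.5-, 2-, 4- and 8-fold among 22772. For the effect in all lines it recovered 30, 39, 50 and 50 of them, with 8 false among 177 calls. For the mutant lines it recovered 0, 30, 45 and 48, for the wildtype lines 0, 29, 49 and 50, and for the difference 1, 3, 46 and 50. In the same order 2, 9 and 9 calls were false, among 125, 137 and 109. The simulated noise was independent between genes and each change was equal in every changed line. The recovery in the real data, where the lines were unequal, may therefore be lower.

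The alternatives were no background subtraction, the deposited log10 ratio, median centring in place of loess, the series matrix, no filter or a strict filter on dim probes, the mean of a gene's probes, each line left out in turn, the slide as a block, and the other list tests. Median centring of each array over the tested genes was added after seeing the data, because median centring over all probes shifted the median of the tested genes by 0.16 (HT1197), 0.14 (HT1376), 0.11 (T24) and 0.16 (5637) on the log2 scale. For DMSO levels, quantile normalisation over all 8 channels and processed intensities scaled to the 75th percentile were tried. Agilent's p-value was used as a filter on the 2-fold counts (under 0.01).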

Results

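The series asks how inhibition of EZH2, the histone methyltransferase of the Polycomb repressive complex PRC2, acts on bladder cancer cells with and without a mutation of ARID1A, a subunit of the SWI/SNF chromatin remodelling complex. RNA of 4 cell lines treated with the EZH2 inhibitor GSK126 (7.5 uM) was set against RNA of the same line treated with DMSO, on 1 array per line. HT1197 and HT1376 are ARID1A mutant and T24 and 5637 are wildtype per the labels, so each group holds 2 lines. In the DMSO channel 26649 (HT1197), 27837 (HT1376), 28033 (T24) and 27847 (5637) of 41000 probes were well above background. In the GSK126 channel the counts were 26161 (HT1197), 30408 (HT1376), 29533 (T24) and 29305 (5637). After filtering, 22772 genes or features were tested. Values are log2(GSK126/DMSO), positive where GSK126 was higher, with the SE of the limma fit. The deposited series matrix has the opposite sign, and its column medians are -0.00368 (HT1197), 0.0242 (HT1376), 0.0107 (T24) and -0.00282 (5637).

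The first comparison asks what GSK126 did in all 4 lines. Genes of mitosis were lower with GSK126, with a median log2 ratio of -0.50 over 43 genes, all of them negative in the mean of the lines. Genes of DNA replication were lower as well (median -0.29, 37 of 39 negative). Genes of cholesterol synthesis (median 0.38, 22 of 26 positive), of autophagy and the lysosome (0.13, 29 of 37) and of antigen presentation (0.18, 20 of 24) were higher, the cholesterol genes mainly in the mutant lines. Among the highest single genes was PODXL, an anti-adhesive sialomucin of the cell surface, at 1.46 ± 0.24 (SE, n = 4). EZH2 itself stayed at -0.10 ± 0.12 (n = 4), and turned to 0.31 with median centring.

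By camera the mitosis list had an adjusted p of 2.23e-18 and the replication list one of 7.11e-13. The adjusted p was 0.647 for both with an estimated correlation. The lines were unequal, with mitosis medians of -0.41 in HT1197, 0.02 in HT1376, -0.58 in T24 and -1.03 in 5637. Of the mitosis genes 0 passed over all genes and 15 passed adjusted over the list alone, among them FOXM1, a transcription factor of mitotic genes (-0.64 ± 0.10), CCNB2, a B-type cyclin (-0.75 ± 0.20), and the kinases PLK1 (-0.72 ± 0.19) and AURKA (-0.65 ± 0.15). Of the replication genes 0 passed over all genes and 4 passed adjusted over the list alone: MCM4, CDT1, TK1 and POLD1. With median centring these values moved toward 0 by more than 1.5 times and kept their sign: the medians were -0.18 for mitosis and -0.03 for replication, and FOXM1 was at -0.35, CCNB2 at -0.24, PLK1 at -0.26 and AURKA at -0.31. With the mean of its probes CCNB2 was -0.32, and the mitosis median without 5637 was -0.29.

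The cholesterol list had medians of 0.54 in HT1197, 0.93 in HT1376, 0.02 in T24 and 0.04 in 5637, the antigen presentation list 0.004, 0.51, 0.12 and 0.14, and the autophagy list 0.14, 0.06, 0.15 and 0.24, in the same order. For the higher lists, camera gave adjusted p-values of 0.000193 (cholesterol), 0.000853 (autophagy and lysosome) and 0.0169 (antigen presentation). These p-values were 0.647, 0.478 and 0.647 as adjusted p with an estimated correlation. No member of the 3 lists passed over all genes. Adjusted over the list alone 0 of the cholesterol, 7 of the autophagy and 5 of the antigen presentation genes passed. The 7 were SQSTM1, an autophagy receptor (0.66 ± 0.07), NPC2, which exports cholesterol from lysosomes (0.67 ± 0.10), CD63, a lysosomal tetraspanin (0.60 ± 0.09), WIPI1, NEU1, NPC1 and, as lower, GLA (-0.45). The 5 were HLA-C (0.93 ± 0.13), HLA-G (0.82 ± 0.11), B2M, the light chain of HLA class I (0.50 ± 0.08), HLA-DMA and, as lower, PSMB10 (-0.32), and with the mean of a gene's probes HLA-C was 0.52 and HLA-G 0.28. With median centring the bright genes were higher still, such as HLA-C at 1.66, B2M at 1.23, NPC2 at 1.36, SQSTM1 at 1.15 and CD63 at 1.35, and CD63 was 0.40 with the deposited log ratio. Fatty acid synthesis genes were also higher (median 0.15, 12 of 18 positive), with 0 members passing over all genes and 5 adjusted over the list alone: SCD, FADS1, ACSL3, ACSS2 and LPIN1. The camera adjusted p of this list was 0.0199, and 0.647 with an estimated correlation. Without HT1376 the antigen presentation (median 0.07, adjusted p 0.171) and fatty acid lists (0.10, 0.0647) had no call, and without HT1197 the fatty acid list had none (0.13, 0.0529). The cholesterol median without HT1376 was 0.21 (adjusted p 0.0264).

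Genes of ribosomal proteins had a median of 0.31, with 36 of 41 positive, 0 passing over all genes and 20 adjusted over the list alone. The camera adjusted p was 1.87e-12, and 0.478 with an estimated correlation. This direction depends on how bright spots are normalised: the median was 0.03 with the deposited log ratio (adjusted p 0.344) and -0.01 with the series matrix (adjusted p 0.594). The 275 genes with a mean log2 brightness over 16 had a median of 0.22 here and of 0.01 with the series matrix. Single bright genes differed in this: RPS28 was 0.89 ± 0.09, but 0.31 with the matrix, 0.51 with the deposited log ratio and 0.45 with the mean of its probes, while FTH1, the ferritin heavy chain, was 0.95 ± 0.09, and 0.77 with the matrix, and HLA-C and B2M were 0.89 and 0.55 with it. With median centring RPS28 was 1.73 and FTH1 1.76.

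A further 7 lists were called, each with an adjusted p of 0.478 or more with an estimated correlation. Metallothioneins (median 0.13, 13 of 13 positive, adjusted p 0.0104), NF-kB target cytokines (0.17, 25 of 32, 0.0129), the integrated stress response (0.08, 18 of 27, 0.0274) and the interferon response (0.12, 35 of 46, 0.0423) were higher. Markers of blood, endothelial and stromal cells, which cancer cell lines should hold at low levels, were higher by a median of 0.09 (13 of 14, adjusted p 0.0251). The call of this list limits what a camera call at the preset correlation can show for the other lists. Subunits of PRC2 (median -0.10, 9 of 11 negative, adjusted p 0.0274) and of SWI/SNF (-0.06, 16 of 24, 0.0274) were lower, but turned to 0.18 and 0.23 with median centring. Neither list was called there (camera adjusted p 0.868 and 0.583). The metallothionein median was -0.08 in HT1197, against 0.41 in HT1376. Each of the 7 calls was lost in at least 1 alternative: the interferon median turned to -0.05 without HT1197 (adjusted p 0.194), and without HT1376 metallothioneins were at 0.07 (0.0954) and NF-kB targets at 0.07 (0.179). Without 5637 the PRC2 list (-0.12, adjusted p 0.214), the SWI/SNF list (-0.07, 0.0704), the stress list (0.07, 0.370) and the blood cell markers (0.08, 0.0704) had no call. In these 7 lists 0 members passed over all genes, and 5 passed adjusted over the list alone: PHF19, a PRC2 accessory subunit (-0.71 ± 0.11), IFITM1, an interferon-induced membrane protein (0.67 ± 0.11), and the stress genes DDIT3 (0.59 ± 0.13), DDIT4 (0.57 ± 0.06) and STC2. With median centring PHF19 was -0.31, IFITM1 1.32 and DDIT4 1.02.

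The other 13 lists had no call. Developmental regulators that Polycomb holds silent in many tissues, the group most directly tied to EZH2, had a median of 0.01 (52 of 95 positive, adjusted p 0.939). PI3K-AKT-mTOR genes (0.01, with a test direction of down), NK-cell ligands (0.07), endoplasmic reticulum chaperones (0.04), heat shock proteins (-0.01, with a test direction of up), the BCL2 family (0.03, with a mean of -0.01 and a test direction of down), hypoxia and glycolysis (0.09) and NRF2 targets (0.07) had adjusted p-values of 0.110 or more. So did CDK inhibitors and p53 targets (-0.06), luminal (-0.02) and basal markers (0.01, with a test direction of down), mesenchymal markers (0.07) and epithelial adhesion genes (-0.02). Of the 132 listed Polycomb targets 95 were measured, and targets well above background on fewer than 2 arrays were left out. Fry's mixed test, of change in either direction, gave the Polycomb list an adjusted p of 0.404 over all lines. In the mutant lines it was 0.0196, where that test called 15 of 27 lists.

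By limma 0 of 22772 genes passed in the 4 lines, with a lowest adjusted p of 0.183, and 3146 had an unadjusted p under 0.05, where chance gives 1139. The other genes named by the rule are given as values. Positive in every line were RASD1, a dexamethasone-induced Ras protein (0.95 ± 0.08), GIPR, the receptor of an incretin hormone (1.18 ± 0.13), SPOCK1 (1.07 ± 0.15), HEY1, a Notch target (0.89 ± 0.13), FHOD3 (0.94), SEL1L3 (1.57 ± 0.27), WLS, which carries Wnt proteins to the surface (0.81), and CHST15 (1.00 ± 0.11). With the mean of a gene's probes RASD1 was 0.60, GIPR 0.59 and CAPRIN1, among the lower genes, -0.23, and with median centring RASD1 was 1.46. Negative in every line were PTTG2 (-0.84 ± 0.12), CBR3 (-0.62), DUT, which keeps uracil out of DNA (-0.61 ± 0.10), DEK (-0.58), TRAIP (-0.52), MST1R (-0.49), DDX39B (-0.48), CENPH, a kinetochore protein (-0.47), CAPRIN1 (-0.47), POLD1, the catalytic subunit of DNA polymerase delta (-0.46), and ITGA6 (-0.43). Median centring moved each of these 11 by over 1.5 times toward 0, and CAPRIN1 (0.05) and ITGA6 (0.03) past it. Probes on hg18 lie at chromosome 7, 130835675 to 130835734 for PODXL and at chromosome 12, 2837583 to 2837642 for FOXM1. With median centring 3607 genes passed by limma, 3548 of them higher, and 523 with each array centred over the tested genes.

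**Figure D1:**
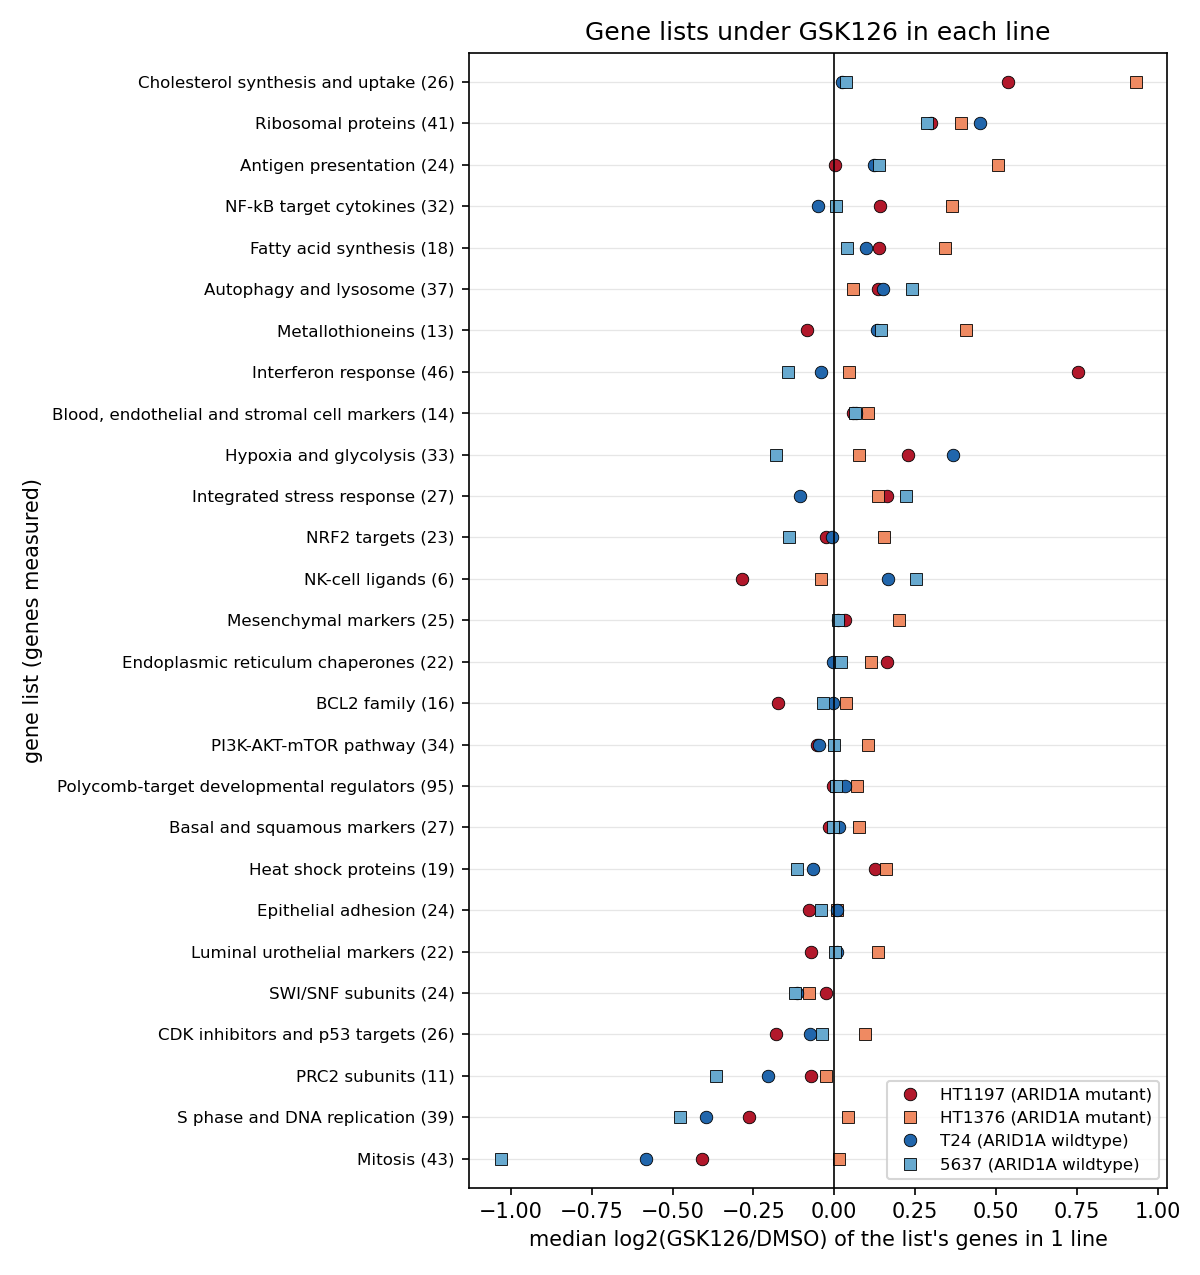
Median log2(GSK126/DMSO) of each gene list (horizontal axis) in each cell line, 1 point per line, with red shades for ARID1A mutant and blue shades for wildtype lines and the number of genes measured in parentheses. Mitosis genes have medians of -0.41, 0.02, -0.58 and -1.03 in HT1197, HT1376, T24 and 5637, and cholesterol genes 0.54, 0.93, 0.02 and 0.04; over all lines the medians of the PRC2 and SWI/SNF lists turn positive with median centring, and the ribosomal median turns negative with the series matrix.

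The second comparison asks what GSK126 did in the ARID1A mutant lines. Genes of the sterol pathway were higher in both HT1197 and HT1376: the cholesterol list had a median of 0.70, with 23 of 26 genes positive and line medians of 0.54 and 0.93. INSIG1, which retains the sterol-sensing machinery in the endoplasmic reticulum, was 3.06-fold higher (log2 1.61 ± 0.23, n = 2), and LSS, which closes the sterol rings, 2.42-fold (1.28 ± 0.11). Genes of fatty acid synthesis (median 0.31, 15 of 18 positive), NF-kB target cytokines (0.25, 29 of 32) and interferon response genes (0.45, 40 of 46) were higher too. Interferon genes were mainly higher in HT1197, with a median of 0.76 there and 0.05 in HT1376.

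By camera the cholesterol list had an adjusted p of 5.71e-11, and one of 0.784 with an estimated correlation. None of its genes passed over all genes and 17 passed adjusted over the list alone, among them HMGCS1, the first committed enzyme of the pathway (1.27 ± 0.16), SQLE and IDI1. Of the fatty acid genes 0 passed over all genes and 9 adjusted over the list alone, among them SCD, the stearoyl-CoA desaturase (1.38 ± 0.16), FADS2, a fatty acid desaturase (1.33 ± 0.09), LPIN1, a phosphatidate phosphatase (1.38 ± 0.08), SREBF1 and, as lower, AGPAT2 (-0.65). The camera adjusted p of this list was 0.000219, and 0.784 with an estimated correlation. Without HT1376 the fatty acid median was 0.14 (adjusted p 0.00684). With the mean of a gene's probes FADS2 was 0.79, LPIN1 0.75 and LSS 0.80.

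The interferon list had a camera adjusted p of 1.22e-05, and 0.852 with an estimated correlation. In it 0 genes passed over all genes and IFITM1, HERC5 (1.16 ± 0.21) and HERC6 passed adjusted over the list alone. Without HT1197 the median was 0.05 and the call was lost (adjusted p 0.585). For the NF-kB list the adjusted p was 0.00014, and 0.784 with an estimated correlation, and with median centring the call was lost (median 0.38, adjusted p 0.0961). Without HT1376 the NF-kB median was 0.14 (adjusted p 0.00854). Here 0 passed over all genes and 6 adjusted over the list alone: the chemokines CXCL1 (1.33 ± 0.29, and 2.29 with the deposited log ratio) and CXCL2 (1.34 ± 0.30, and 2.12), the cytokine IL11, TNFAIP2 (0.89 ± 0.17), NFKBIA and RELB.

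Mitosis genes had a median of -0.17 (38 of 43 negative, adjusted p 0.000219) and replication genes one of -0.12 (29 of 39, 0.00336). The adjusted p was 0.852 for both with an estimated correlation, and 0 genes passed over all genes or adjusted over the list alone. Both medians turned positive with median centring, to 0.23 and 0.28, with no call (camera adjusted p 0.870 and 0.0675). Without HT1197 the mitosis median was 0.02 (adjusted p 0.740) and the replication median 0.04 (0.691). Heat shock proteins were higher by a median of 0.15 (14 of 19, adjusted p 0.0470, and 0.784 with an estimated correlation), with 0 passing over all genes and HSPA8 (0.68 ± 0.12, but 0.39 with the deposited log ratio and 1.47 with median centring), HSPE1 and HSPH1 passing adjusted over the list alone. The heat shock call was lost with the deposited log ratio (median 0.09, adjusted p 0.227) and with any line left out (adjusted p 0.0518 to 0.218). Ribosomal protein genes had a median of 0.30 (32 of 41 positive, 0 passing over all genes and 18 adjusted over the list alone, of which RPS9 was lower at -0.60). The adjusted p was 0.00014, and 0.784 with an estimated correlation, but the median turned to -0.11 with the series matrix.

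By limma 0 of 22772 genes passed in the mutant lines, with a lowest adjusted p of 0.122, while 4377 had an unadjusted p under 0.05. Values of 2 or more in the mean of both lines were seen for MMP1, a collagenase (2.28 ± 0.33), LMO2, a transcriptional cofactor (2.21 ± 0.36), SPINK1, a trypsin inhibitor (2.21 ± 0.46), DEFB103B, an antimicrobial defensin (2.13 ± 0.33), and SEL1L3 (2.09 ± 0.23). PODXL was 1.92 ± 0.20 and SLC12A7, a potassium-chloride cotransporter, 1.89 ± 0.19, or 0.77 with the mean of its probes. Lower in both lines were CAPN6, a calpain-like protein (-1.40 ± 0.09), SNRPB, a core spliceosome protein (-1.32 ± 0.26, and -0.87 with median centring), CAPN1 (-1.22 ± 0.20, and -0.74 with the mean of its probes), KRT33A (-1.14), POLR2E, an RNA polymerase subunit (-1.07), ISYNA1 (-0.80 ± 0.11), EIF2AK4 (-0.77, and -0.42 with median centring) and GLTP (-0.72). The probes of 4 keratin 8 pseudogenes, KRT8P24, KRT8P8, KRT8P22 and KRT8P23, lay between -1.24 and -1.09. KRT8 itself was -1.02 ± 0.17, or -0.61 with median centring, and probes of such similar sequences may not be separate measurements. EZH2 was 0.13 ± 0.10, ARID1A -0.07 ± 0.14 and PIK3IP1, an inhibitor of PI3K, -0.07 ± 0.09. The PIK3IP1 probe lay near background in HT1197 (6.73 in DMSO), which limits its ratio in that line. With median centring EZH2 was 0.63 and ARID1A 0.25, and without HT1197 ARID1A was 0.18. In the fit without HT1197 494 genes passed and without HT1376 1196 passed, as the lone line is then assumed to vary like the wildtype lines. With median centring 4243 passed, or 1005 when centred over the tested genes.

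The third comparison asks what GSK126 did in the ARID1A wildtype lines. Genes of the cell cycle were lower in T24 and 5637. The mitosis list had a median of -0.84 with 43 of 43 genes negative, and the replication list -0.45 with 37 of 39 negative. TK1, the thymidine kinase of S phase, was lower by 1.89-fold (log2 -0.92 ± 0.10, n = 2), RRM1, a subunit of ribonucleotide reductase, by 2.07-fold (-1.05 ± 0.12) and CDCA5, a regulator of sister chromatid cohesion, by 2.01-fold (-1.01 ± 0.10). SLC14A1, a urea transporter, was 5.23-fold higher (2.39 ± 0.32).

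By camera the adjusted p was 3.46e-27 for mitosis and 2.48e-19 for replication, and 0.5995 for both with an estimated correlation. No gene of either list passed over all genes. Adjusted over the list alone 36 mitosis and 26 replication genes passed, among them UBE2C, which loads ubiquitin onto mitotic cyclins (-1.17 ± 0.30), BUB1, a spindle checkpoint kinase (-1.11 ± 0.23), CCNB2 (-1.10 ± 0.20), MAD2L1 (-0.88 ± 0.08) and RRM2 (-0.93 ± 0.26). The medians were -0.50 and -0.25 with median centring, which brought TK1 to -0.33, RRM1 to -0.62 and UBE2C to -0.76, with the sign kept. With the mean of their probes CCNB2 was -0.49 and RRM2 -0.48.

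Autophagy and lysosome genes were higher (median 0.20, 30 of 37 positive, adjusted p 0.000165, and 0.5995 with an estimated correlation), with 0 passing over all genes and 7 adjusted over the list alone: SQSTM1 (0.73 ± 0.09), the cathepsins CTSA, CTSB and CTSD, ATP6AP1, NPC2 and CD63. PRC2 subunits were lower (median -0.32, 8 of 11 negative, adjusted p 0.0291, and 0.5995 with an estimated correlation), but lay at 0.02 with median centring. RBBP7 (-0.44 ± 0.08), PHF19 (-0.75 ± 0.17) and AEBP2 (-0.41 ± 0.08) passed adjusted over the list alone and 0 over all genes, and with median centring RBBP7 turned to 0.02, AEBP2 was -0.11 and PHF19 -0.40. The mean of its probes put AEBP2 at -0.23. Ribosomal protein genes had a median of 0.32 (40 of 41 positive, adjusted p 1.16e-13, and 0.5995 with an estimated correlation, 0 passing over all genes and 14 adjusted over the list alone), but the median was 0.07 with the series matrix (adjusted p 0.469). Without 5637 the PRC2 call was lost (median -0.21, adjusted p 0.173).

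By limma 0 of 22772 genes passed in the wildtype lines, with a lowest adjusted p of 0.237, and 3093 had an unadjusted p under 0.05. Among the highest values were TGFBI, a secreted matrix protein (1.21 ± 0.22), the collagen-binding integrin ITGA11 (1.37 ± 0.14) and the secreted protease HTRA1 (1.32 ± 0.17). PMEPA1, a TGF-beta target, was 1.43 ± 0.37, VDR, the vitamin D receptor, 1.36 ± 0.23, WFDC2 1.67 ± 0.19, HTN3 1.86 ± 0.34, CNIH3 1.40 ± 0.20 and CHST15 1.09 ± 0.16. KLK10 was not well above background in DMSO and by its brightest probe was at least 2.18-fold higher with GSK126. Its log2 ratio was 1.19 here, 0.66 with the mean of its probes and 2.91 with the deposited log ratio. The mean of its probes put SLC14A1 at 1.38. Further low values were IFIT2, an interferon-induced protein (-1.41 ± 0.46), CAV1, the caveolar coat protein (-1.18 ± 0.18), SPC25 (-1.09 ± 0.17), HMGB2 (-1.05 ± 0.20, and -0.54 with median centring), PTTG2 (-1.001 ± 0.141), CIT (-0.98 ± 0.14) and the checkpoint kinase CHEK1 (-0.94 ± 0.09). EZH2 was -0.34 ± 0.10, and -0.01 with median centring, ARID1A 0.16 ± 0.14, and 0.41 with median centring, and PIK3IP1 0.36 ± 0.09, 0.60 with median centring and 0.24 with the mean of its probes. With the deposited log ratio 3 genes passed, of which FGB and FGG have a symbol and were too dim in DMSO for a size, and with median centring 492 passed.

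The fourth comparison asks whether the effect differed by ARID1A status, as the mean of the mutant minus that of the wildtype lines. Cholesterol genes were 0.76 higher in the mutant lines in the median (22 of 26 positive). LSS was 1.21 in HT1197 and 1.35 in HT1376 against -0.12 in T24 and -0.42 in 5637, a difference of 1.55 ± 0.15, or 0.79 with the mean of its probes, and SQLE, the squalene epoxidase, differed by 1.22 ± 0.13. Mitosis genes differed by a median of 0.68 (39 of 43 positive) and replication genes by 0.36 (34 of 39), being lower in the wildtype lines. Interferon response genes differed by 0.55 (39 of 46), but by 0.27 without HT1197 and 1.04 without HT1376, and CD86, a costimulatory ligand of T cells, by 2.15 ± 0.29.

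By camera the adjusted p was 6.63e-09 for cholesterol, 2.24e-09 for mitosis, 4.72e-07 for replication and 3.21e-06 for interferon. For each list the adjusted p was 0.951 with an estimated correlation. No gene of these 4 lists passed over all genes, and 16 cholesterol genes, of which NSDHL was lower in the mutant lines (-0.41), and 0 of the other lists passed adjusted over the list alone. Without HT1376 the median difference was 0.41 for mitosis (adjusted p 0.00155) and 0.13 for replication (0.0105), and without 5637 it was 0.41 for mitosis (1.55e-06). BUB1 differed by 1.05 ± 0.32 and RRM1 by 0.81 ± 0.17. In the interferon list HERC5 differed by 1.69 ± 0.29, RIGI, a sensor of viral RNA, by 1.56 ± 0.41 and IFIT2 by 2.03 ± 0.65, while IFI6 went the other way at -1.55 ± 0.30, or -0.61 with the mean of its probes. Heat shock proteins (median 0.30, 15 of 19 positive, adjusted p 0.00164), fatty acid synthesis (0.26, 14 of 18, 0.00192) and NF-kB target cytokines (0.22, 24 of 32, 0.00495) were also higher in the mutant lines, with an adjusted p of 0.951 each with an estimated correlation. In these 3 lists 0 genes passed over all genes, and FADS2 (1.08 ± 0.12) and LPIN1 (1.00 ± 0.12) passed adjusted over the list alone, and with the mean of their probes were 0.65 and 0.48. The NF-kB call was lost with median centring (median 0.01, adjusted p 0.666) and with the series matrix (0.05, adjusted p 0.493), and without HT1376 the NF-kB (0.11, adjusted p 0.0615) and fatty acid (0.24, 0.0615) calls were lost. CXCL1 differed by 1.63 ± 0.41, or 2.69 with the deposited log ratio, and TNFAIP2 by 1.25 ± 0.25.

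**Figure D2:**
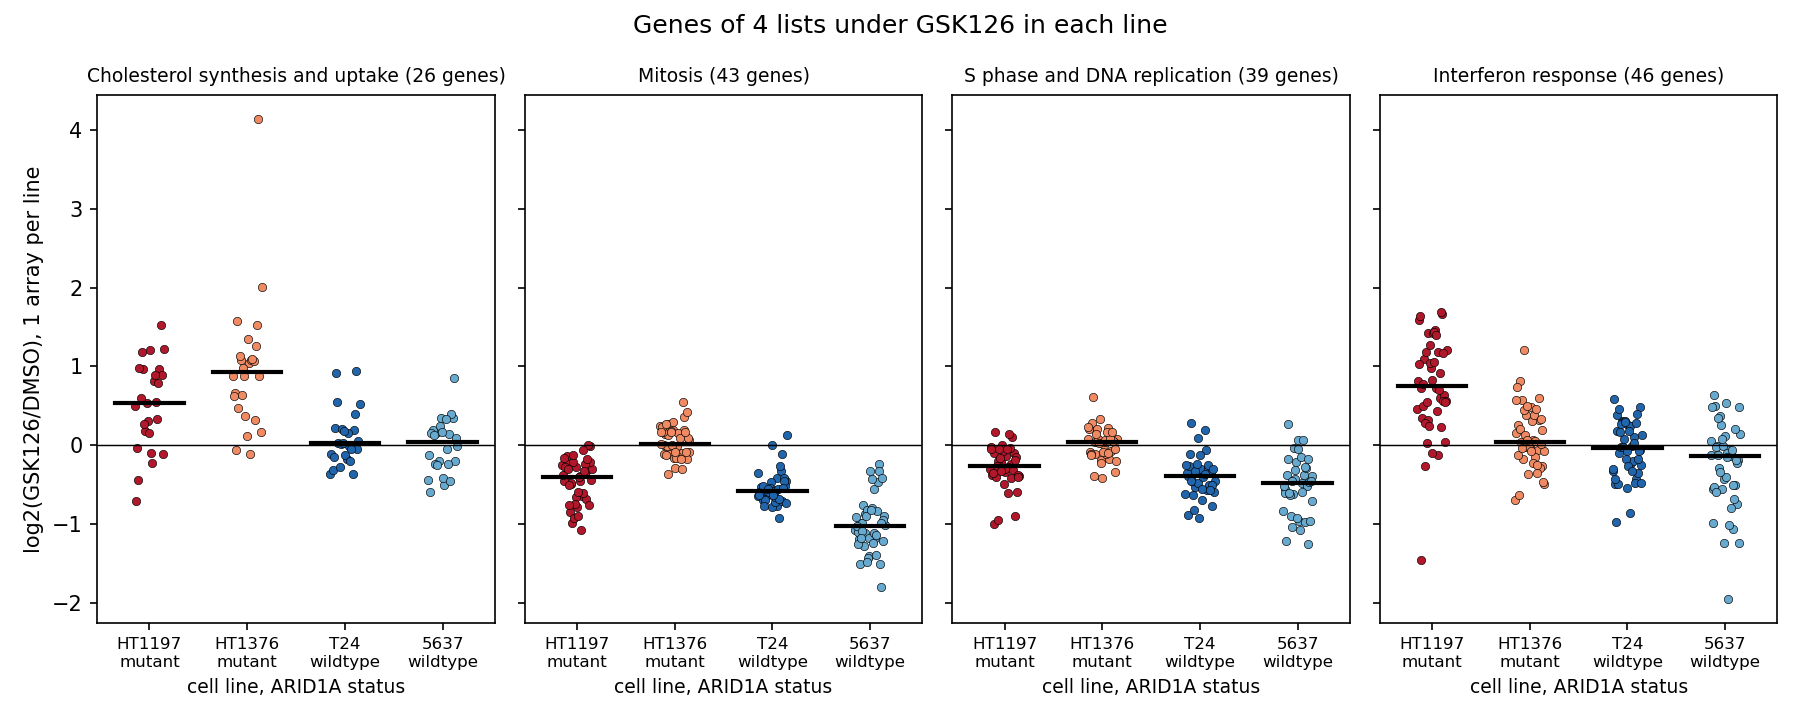
Log2(GSK126/DMSO) of the genes of 4 lists in each line (vertical axis), 1 point per gene and array, with the list's median as a bar. Cholesterol genes have medians of 0.54 and 0.93 in the mutant and 0.02 and 0.04 in the wildtype lines, mitosis genes -1.03 in 5637 against 0.02 in HT1376, and interferon genes 0.76 in HT1197 alone; the mutant medians of the mitosis and replication lists turn positive with median centring.

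By limma 0 of 22772 genes passed for the difference, with a lowest adjusted p of 0.296, and 3493 had an unadjusted p under 0.05. Further genes higher in both mutant lines than in both wildtype lines were LMO2 (2.45 ± 0.51), DEFB103B (2.31 ± 0.47), LAMP3, a lysosomal membrane protein (1.83 ± 0.31), LRRC2 (1.75 ± 0.29), RPA4 (1.71 ± 0.22), CABP7 (1.67 ± 0.20, and 2.55 with the deposited log ratio), BLVRA, biliverdin reductase (1.54 ± 0.19), ICAM2 (1.34 ± 0.12, and 2.18) and AREG, an EGF receptor ligand (1.32 ± 0.13). Lower in the mutant lines were SLC14A1 (-2.29 ± 0.46, and -1.40 with the mean of its probes), CLU, an extracellular chaperone (-1.67 ± 0.37), CAPN6 (-1.44 ± 0.12), TPD52L1 (-1.34 ± 0.19), ITGA11 (-1.30 ± 0.20), HTRA1 (-1.20 ± 0.24, and -0.51 with the deposited log ratio), SLC22A23 (-1.11 ± 0.16) and MMP13, a collagenase (-1.07 ± 0.16, and -2.15). The fibrinogen chains FGB and FGG were lower too, but too dim in DMSO for a size, and a probe of the keratin 18 pseudogene KRT18P28 was at -2.30 ± 0.68. EZH2 differed by 0.47 ± 0.15, PIK3IP1 by -0.43 ± 0.12 and ARID1A by -0.23 ± 0.20, or 0.03 without HT1197, where a dimmer ARID1A probe gave other values, -0.48 in HT1197 and 0.20 in 5637. The slide and the genotype cannot be told apart, since no slide held lines of both groups. In the fits without HT1197 and without HT1376 143 and 601 genes passed.

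The lines were also described by themselves, without a test. Genes at least 2-fold higher or lower with GSK126 numbered 439 in HT1197, 387 in HT1376, 152 in T24 and 161 in 5637. In HT1376 379 of them and in T24 150 were higher, while in HT1197 308 and in 5637 112 were lower. The split of HT1197 and 5637 depends on the scaling: 29.8% and 30.4% were higher here, 95.5% and 94.0% with median centring, 86.0% and 74.9% with centring over the tested genes, 43.1% and 48.6% with the deposited log ratio and 40.8% and 40.5% with the series matrix. In HT1376 and T24 83.7% or more were higher under each of these. The highest genes of HT1197 were TM4SF19 (2.63), PDE2A, a cyclic nucleotide phosphodiesterase (2.08), and SUN3 (1.86), and the lowest were probes of the keratin 18 pseudogenes KRT18P28 (-2.53), KRT18P41 (-2.52) and KRT18P21 (-2.47). HT1376 had GPNMB, a glycoprotein of lysosomes and melanosomes (4.12), and SPON2 (4.10) near the top and HES5, a Notch target (-1.59), CAPN6 (-1.47) and INPP1 (-1.38) at the bottom. In T24 DMBT1 (3.70) and SLC14A1 (3.08) were highest, and the lowest ANXA3 (-1.06), ISG20 (-0.97) and DENND2A (-0.94). In 5637 the highest were ACKR3, a scavenging chemokine receptor that was not well above background in DMSO (at least 3.84-fold), BEX2 (1.84) and MMP10 (1.81), and the lowest HOXB8 (-2.31), CTSZ (-2.28) and SRSF6 (-2.06).

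Of these genes, 35 were higher in both mutant lines, where independent lists would share 2.18, among them INSIG1, LSS, LPIN1, SCD and FADS2. Lower in both were 2 (0.108 expected), CAPN6 and a feature without a gene symbol. Higher in both wildtype lines were 17 (0.323 expected), among them VDR, TGFBI and ITGA11, and 0 were lower in both (0.00984 expected) or at least 2-fold apart in the same direction in all 4 lines. Mixed pairs shared higher genes as well: 27 in HT1376 and T24 (2.5 expected), 14 in HT1376 and 5637 (0.816), 5 in HT1197 and T24 (0.863) and 3 in HT1197 and 5637 (0.282). They shared 0 lower genes, where 1.51 were expected for HT1197 and 5637. At least 2-fold apart in opposite directions were 8 genes in HT1197 and 5637, 5 in HT1197 and T24, 4 in HT1376 and 5637 and 0 in the other 3 pairs. Across genes, which are not independent replicates, the log2 ratios of HT1197 and HT1376 had a Pearson's r of 0.453 (Spearman's rho 0.476) and those of T24 and 5637 one of 0.453 (rho 0.437). In the 4 pairs of a mutant and a wildtype line r was 0.132 (HT1197 and T24), -0.0683 (HT1197 and 5637), 0.269 (HT1376 and T24) and 0.0627 (HT1376 and 5637). Pairs of the same status also shared a slide. With median centring the mean r was 0.603 in pairs of the same status and 0.325 in mixed pairs, against 0.453 and 0.0987 here.

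The last comparison asks how the DMSO-treated mutant and wildtype lines differed before any inhibitor. Epithelial and squamous genes were higher in the mutant lines. CDH1, the adhesion protein E-cadherin, was not well above background in the wildtype lines and at least 437-fold higher in the mutant lines (adjusted p 0.0476), SPRR3, a protein of the cornified envelope, 220-fold higher (log2 difference 7.78 ± 0.25, adjusted p 0.0343) and UPK1B, a uroplakin of the bladder lining, at least 66.8-fold (0.0343). Higher in the wildtype lines were GNG11, a G protein subunit (-7.77 ± 0.61, adjusted p 0.0482), TPM2, a tropomyosin (-7.25 ± 0.21, 0.0343), the homeobox genes HOXB6 (-7.36 ± 0.46, 0.0378) and HOXB2 (-6.16), and FOXA1, a luminal transcription factor, by at least 85.4-fold (0.0343). In HT1376 HOXB6 (6.55) and HOXB2 (6.52) lay near FOXA1 (6.47), which was not well above background there, so their differences may be larger than given. The same holds in HT1197 for GNG11 (6.40) and, named below, SLFN11 (6.46) and CDH13 (6.72), with FOXA1 at 6.72. Each gene named here was separated in all 4 lines.

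By limma 166 of 22772 genes passed, 83 higher in each group, and 3804 had an unadjusted p under 0.05. Genes of epithelial adhesion were higher in the mutant lines (median 2.74, 21 of 24), with 6 passing over all genes (CDH1, CLDN4, CLDN7, OVOL1, OVOL2 and ST14) and 19 adjusted over the list alone. Basal and squamous markers were higher (2.18, 24 of 27; CDH3 and SPRR3 passed, and 10 adjusted over the list alone), as were luminal markers (1.46, 15 of 22; FGFR3, UPK1B and VGLL1 passed as higher and FOXA1 as lower, and 10 adjusted over the list alone). Replication genes were 1.24 higher in the median (37 of 39; 0 passed, and 20 adjusted over the list alone). The camera adjusted p was 1.06e-14 for adhesion, 5.58e-07 for basal, 0.000323 for luminal and 4.52e-14 for replication genes. In the same order the adjusted p with an estimated correlation was 0.314, 0.314, 0.339 and 0.314. NF-kB target cytokines (median -1.80, 0 of 32 higher in the mutant lines, adjusted p 3.84e-06), interferon (-1.42, 4 of 46, 2.42e-05) and hypoxia genes (-1.06, 4 of 33, 0.00031) were lower in the mutant lines, with an adjusted p of 0.732 each with an estimated correlation. Polycomb-target regulators were lower by 0.24 in the median (34 of 95 higher in the mutant lines, adjusted p 0.000273, and 0.534 with an estimated correlation), with 9 passing over all genes, 8 of them higher in the wildtype lines, among them HOXB5, HOXB8, HOXD10 and PAX8. Cholesterol genes were 0.75 higher in the mutant lines at DMSO (22 of 26, adjusted p 0.000336, and 0.641 with an estimated correlation) and mitosis genes 0.46 higher (34 of 43, 0.00348, and 0.862). Metallothioneins (-1.45, 2 of 13 higher in the mutant lines) and antigen presentation genes (-0.83, 6 of 24; HLA-DPB1 passed) were lower in the mutant lines and heat shock genes higher (0.61, 18 of 19), with camera adjusted p-values of 0.000414, 0.00882 and 0.00254, and adjusted p of 0.619, 0.534 and 0.534 with an estimated correlation.

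Further genes higher in the mutant lines were KLK8 (at least 142-fold), KDF1 (at least 121-fold), VGLL1 (at least 75.7-fold), IL20RB (6.89), TNS4 (6.88), TINCR (6.53), MFAP5 (at least 101-fold), TPD52L1 (6.53) and the drug exporter ABCG2 (6.33), and in the wildtype lines CDH13 (-6.83), RNF130 (at least 73.1-fold), NRP1 (at least 60.1-fold), COL18A1 (-5.96), PAX8 (-5.89), COL5A2 (-5.73) and SLFN11 (-5.66). ARID1A RNA differed by -0.17 ± 0.77 (adjusted p 0.947), EZH2 by 0.34 ± 0.49 (0.794) and PIK3IP1 by -1.75 ± 0.83 (0.4125). PIK3IP1 lay near background in HT1197 (6.73), so its difference may be larger than given. T24 and 5637 had the most similar DMSO profiles of the 6 pairs, with an r of 0.967 across genes and 106 genes at least 8-fold apart, against 0.926 and 418 for HT1197 and HT1376. The identity of the lines is that of the labels and was not tested, so it is not known how far T24 and 5637 count as independent replicates. The SE and p-values of every comparison rest on this. For the mutant lines they do so because the group means model pools the spread of both groups. So does the reading of CDH1, which was near background in both (6.29 in T24 and 6.24 in 5637). The slide and the genotype cannot be told apart here either, and with any 1 line left out 0 genes passed by limma, with lowest adjusted p-values of 0.0642 to 0.353.

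**Figure D3:**
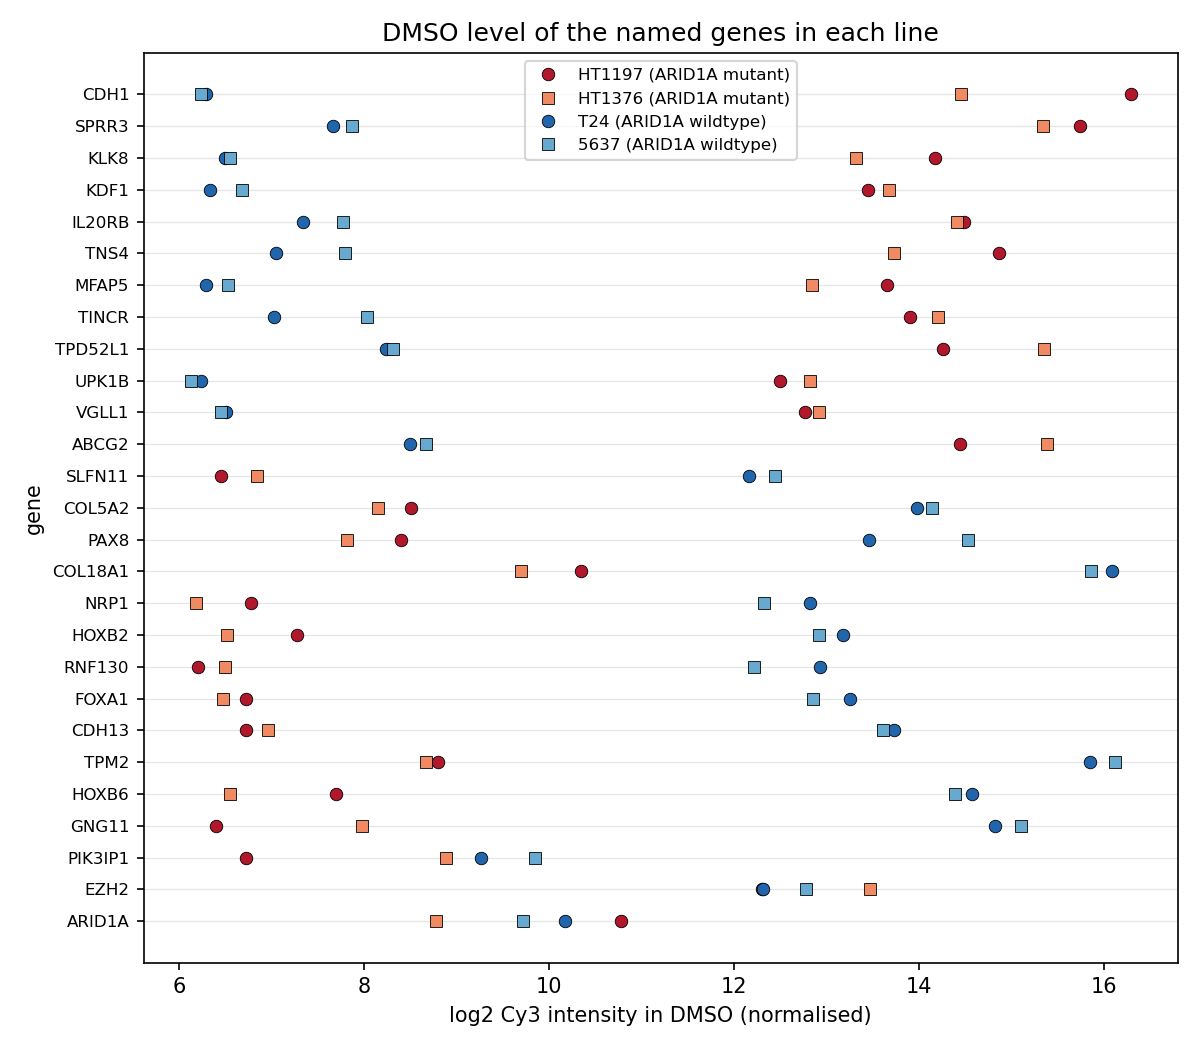
Normalised log2 Cy3 intensity in DMSO (horizontal axis) of the named genes in each line, 1 point per array, with red shades for ARID1A mutant and blue shades for wildtype lines. CDH1 lies at 16.29 and 14.45 in the mutant lines and at 6.29 and 6.24 in the wildtype lines, while ARID1A and EZH2 overlap between the groups.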

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

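The tests of slide or labelling batch, of dye bias and of the nearest genes in brightness were chosen only after the result was seen. For 7 gene lists the effect of GSK126 differed between the ARID1A mutant and wildtype lines by limma's camera on the difference. The median log2 difference, mutant minus wildtype, was 0.76 for cholesterol synthesis and uptake (adjusted p 6.63e-09), 0.68 for mitosis (2.24e-09), 0.55 for the interferon response (3.21e-06) and 0.36 for replication (4.72e-07). It was 0.30 for heat shock proteins (0.00164), 0.26 for fatty acid synthesis (0.00192) and 0.22 for NF-kB target cytokines (0.00495). With an estimated correlation the adjusted p was 0.951 for all 7 lists, and 0 lists passed by fry (lowest adjusted p 0.0518). The NF-kB call was lost with median centring, with the series matrix and without HT1376, and the fatty acid call without HT1376. HT1197 carries much of the interferon difference: the line medians were 0.76 (HT1197), 0.05 (HT1376), -0.04 (T24) and -0.14 (5637), and the difference was 0.27 without HT1197.

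Cholesterol genes were higher with GSK126 in both mutant lines (medians 0.54 and 0.93) and near 0 in both wildtype lines (0.02 and 0.04). A brightness-dependent bias is argued against: the list's median difference of 0.76 was at percentile 100 of 10000 random lists matched on brightness, whose central 95% ran from -0.131 to 0.196. With the series matrix the median difference was 0.894. The list was tested because it was called, and the match to the nearest genes, used for ribosomal genes below, was not run for it. An artefact of array position is argued against as well, since the covariance of repeated-spot residuals between the arrays of a slide was 0.0353 of that of the gene values on the mutant and 0.0406 on the wildtype slide. The slide or labelling batch and the genotype cannot be told apart, as 0 slides hold lines of both groups. A response of lipid synthesis that depends on ARID1A may therefore be one explanation, and other differences between the 4 lines, such as the DMSO level of these genes (0.75 higher in the mutant lines), stay open untested.

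Mitosis and replication genes were lower with GSK126 in the wildtype than in the mutant lines, with a median difference of 0.471 over the 82 genes of both lists. Percentile 100 of the brightness-matched lists (central 95% from -0.0522 to 0.120) argues against a brightness-dependent bias. So does the series matrix, where the mean of both lists' medians was 0.589, against medians of 0.68 (mitosis) and 0.36 (replication) here. The match to the nearest genes was not run for these lists either. The residual covariance ratio of at most 0.0406 argues against array position. The slide or labelling batch cannot be told apart from the genotype here (0 slides with both groups), and slower growth of the wildtype lines with GSK126 is a possible explanation that was not measured. HT1197 (-0.41) lay nearer to T24 (-0.58) than to HT1376 (0.02) in its mitosis median, so the lines of a group were not alike, and without HT1376 the differences were 0.41 for mitosis and 0.13 for replication.

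Ribosomal protein genes were higher with GSK126 in each line, with medians of 0.30 (HT1197), 0.39 (HT1376), 0.45 (T24) and 0.29 (5637). A brightness-dependent bias is a possible source: the call was lost with the deposited log ratio (0.03) and the series matrix (-0.01). The 275 genes with a mean log2 brightness over 16 had a median of 0.22 here, against 0.01 with the matrix. They include ribosomal genes such as RPS28. The matched lists put the median of 0.31 at percentile 100 (central 95% from 0.0306 to 0.206), a value set in advance to count against this bias, but 38 of the 41 genes were in the brightest group, which spans 2.13 in log2 brightness. Against lists drawn from each gene's 20 nearest genes in brightness the median was at percentile 36.1 (central 95% from 0.263 to 0.463). With 50 nearest genes it was at 67.9. Only the listed genes were kept out of these draws, so other ribosomal protein genes may be among them. The draws therefore cannot tell a brightness bias from an effect on ribosomal genes. Dye bias of single genes and an effect of GSK126 cannot be told apart by the ratio of the lowest to the highest line (0.635, bootstrap bounds -0.0153 to 0.726), since no array exchanged the dyes.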

How the results depend on the processing

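Median centring over the tested genes was chosen only after the results were seen, and the other alternatives before. Median centring of all probes, which assumes no trend with brightness, gave 3607 passing genes by limma for all lines, 4243 for the mutant and 492 for the wildtype lines, and centring over the tested genes gave 523 and 1005 for all and mutant lines. With the deposited log ratio 3 genes passed for the wildtype lines: FGB, FGG and a feature without a symbol. The other normalisations, filters, the mean of probes and eBayes with trend and robust gave 0 passing genes by limma for the 4 contrasts, as did the slide as a fixed or random term for all lines, where it was run. For all lines 1981 to 4239 genes had an unadjusted p under 0.05 under these. Leaving out each line gave 0 to 1196 for the mutant lines and 0 to 601 for the difference. The highest counts came without HT1376, where the lone mutant line is assumed to vary like the wildtype lines, which its construction brings.

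Genes at least 2-fold apart numbered 3812 over the lines with the deposited log ratio, 2882 with median centring, 1838 with centring over the tested genes and 5225 at 1.5-fold, against 1139, and the error-model p removed none. Shared in both mutant lines were 220, 279 and 161 with the first 3 of these, against 37, and in both wildtype lines 100, 137 and 73, and 10 with the strict filter, against 17. With median centring the mean correlation was 0.603 for lines of the same status and 0.325 for mixed pairs.

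Gene lists called in all lines numbered 8 with the deposited log ratio and 8 to 13 with a line left out, against 14. For the mutant lines 13 were called with median centring, 7 without background subtraction, 6 with the deposited log ratio and 6 with the mean of probes, against 8. For the wildtype lines the count was 3 with the deposited log ratio, 9 with median centring, 9 with the series matrix and 5 to 9 with a line left out, against 5, and for the difference 5 to 12 with a line left out, against 7. An estimated correlation gave 0 lists in each of the 4 contrasts and fry 0, and fry's mixed test, of change in either direction, called 10 (all), 15 (mutant), 8 (wildtype) and 7 (difference).

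Reversed directions with median centring over all lines were PRC2 (0.176, camera adjusted p 0.868), SWI/SNF (0.234, 0.583) and blood cell markers, whose test turned down at a median of 0.0913 (0.868). In the mutant lines replication (0.280, 0.0675) and mitosis (0.234, 0.870) reversed. With the series matrix ribosomal genes reversed over all lines (-0.00731, 0.594) and in the mutant lines (-0.106, 0.141). None of these lists was called in the reversed direction. Median centring also shifted the median of all tested genes, by 0.11 (T24) to 0.16 (HT1197). The interferon median over all lines ran from -0.0488 without HT1197 to 0.220 without 5637. The cause was not tested for these, except that median centring keeps the trend with brightness that loess removes.

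DMSO genes numbered 90 with no filter (more genes tested), 26 with the strict filter (fewer genes tested), 648 with processed intensities at the 75th percentile and 0 with any line left out, against 166. The 166 kept their sign under each alternative, of which 78 were measured under the strict filter. Of 516 values of named genes, 225 moved with median centring (27 of opposite sign), 99 with the deposited log ratio, 81 with the mean of probes (4 of opposite sign), 56 with the series matrix and 1 without background subtraction. Of opposite sign were 11 without HT1197 and 6 without each of HT1376, T24 and 5637. Signal over background limits ratios of dim probes, of which 399 genes were dim in both groups in DMSO.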

Other observations

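Of the hypoxia and glycolysis list, which was not called for all lines (camera adjusted p 0.110), 2 members are given per line. VEGFA, a hypoxia-induced growth factor, was 0.49 in HT1197, 0.90 in HT1376, 1.05 in T24 and 0.52 in 5637, and NDRG1, a hypoxia-induced protein, was 0.44, 1.08, 1.25 and 0.36 in the same order. With the mean of their probes the averages over the lines were 0.36 for VEGFA and 0.44 for NDRG1. Neither passed over all genes by limma, and both passed adjusted over the list alone. Some members of lists without a call split by genotype: IRX5, a homeobox regulator, was 1.27 and 0.86 in the mutant and -0.31 and -0.82 in the wildtype lines (a difference of 1.63, or 0.68 with the mean of its probes), IRS1, an insulin receptor substrate, 0.29 and 0.81 against -0.27 and -0.79 (1.08, or 1.83 with the deposited log ratio), and CD44, a hyaluronan receptor, 0.64 and 0.77 against -0.14 and -0.35. These genes are examples from the Polycomb-target, PI3K-AKT-mTOR and basal lists. In these lists 41 of 95, 16 of 34 and 14 of 27 genes differed the other way. The keratins of simple epithelia KRT8 (-1.36, -0.68, -0.07 and -0.04) and KRT7 (-1.83, -0.30, -0.14 and -0.12) were lower in HT1197 than in the other lines.

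In DMSO the correlation across genes was 0.890 for HT1197 and T24, 0.881 for HT1197 and 5637, 0.8998 for HT1376 and T24 and 0.882 for HT1376 and 5637, with 769, 812, 681 and 839 genes at least 8-fold apart. In the GSK126 channel the r was 0.926 for the mutant and 0.967 for the wildtype pair. Genes are not independent replicates, and no test was made of these values.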
